A study of Homo sapiens with 5 samples.

How the data were processed

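Transcript levels were measured in MCF-7 human breast cancer cells transfected by a Lipofectamine reagent with an empty vector, wild-type XIAP, XIAP H467A, XIAP delta-RING or XIAP NLS. Total RNA was taken 24 h later, and each of the 5 samples was labelled with biotin and hybridised to 1 Clariom S human array, per the labels. The deposited values are RMA expression values per probe set, made in Transcriptome Analysis Console, per the labels and the submitters' processing notes. RMA subtracts background, makes the arrays' distributions alike and summarises the probes of a set, and its options and the software version are not given in the sources used here. That the deposited values are on a log2 scale was inferred from their range, which lies within 1.89 and 14.00 over the 5 arrays. The 5 columns had slightly different medians, between 6.52 and 6.65 over named genes, and different spreads, so their distributions were not fully equal. No scanner files were used. No 2 arrays were copies of each other: the empty vector and NLS arrays, the closest pair, correlated at 0.984 across the genes kept for the comparisons, held 80 identical values among all 24351 probe sets and were kept as separate samples, and other pairs held 0 or 1 identical values.

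Gene names came from the platform annotation paired with the probe sets. Of 24351 probe sets, 17709 had 1 gene symbol, 0 had several and 6642 were not named here. All 17709 were matched by gene identifier to a RefSeq table of the human assembly, which changed 0 symbols. For the 20 genes with several probe sets the set with the highest mean over the 5 arrays was used, which left 17687 genes, and the probe sets of 1 gene passed 2-fold in opposite directions. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. Counts and named genes were taken from the 9911 kept genes, whose highest value over the 5 arrays reached the median of all values (6.57).

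No test was run, since with 1 array per condition no spread between replicates can be estimated. An additive fit of localization and RING would leave 1 residual degree of freedom, and it would take as noise the contrast of wild type and delta-RING with H467A and NLS, which is itself a comparison here. Each comparison is a difference of deposited log2 values, and genes past 2-fold were counted in each direction. The comparisons were each construct against the empty vector, each altered construct against wild type, genes past 2-fold in all 4 constructs, and the 3 ways to split the 4 constructs into pairs, by localization, by RING domain and with no single named factor. That last split is the interaction of localization and RING. A gene separated a split when the lowest value of a pair lay above the highest of the other by at least 1.5-fold. For 31 gene lists with 508 genes, of which 452 were measured and 56 were not named by the annotation, the median difference was set beside 10000 random lists of the same size, matched in 20 bins of mean level. A list is said to stand apart at or beyond percentiles 1 and 99, which describes these arrays and is not a p-value. All measured members entered, without the filter on dim genes.

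The genes named in the text follow a fixed rule. They are XIAP and the IAP family, up to 10 genes each way with the largest differences past 2-fold per construct against the empty vector, up to 5 each way against wild type, the 10 each way with the largest smallest difference in all 4 constructs, up to 10 each way with the largest gap per split, and up to 4 members of each described list. The rule, the lists, the comparisons and the alternatives were fixed before the data were examined, except where the text says otherwise. TNFAIP3, MX2 and the genes of the lists in the last part were chosen after their values were seen. Genes named for the split without a single named factor were chosen after their values were seen, by the rule of the other splits.

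Comparisons that share the empty vector array were set beside 100 simulations of unchanged arrays, in which each array had independent noise from a t distribution with 4 degrees of freedom, scaled to each array's robust spread around the gene means among genes of like level. That noise contains whatever real differences the arrays hold, so it is an assumed level and not a measured one. In a further simulation the observed deviations of each array from the mean were shuffled across genes of like level. The scripts were tested on simulated arrays of 17687 genes with 50 genes changed at each of several sizes. For wild type against the empty vector, 56% of genes raised by 1 log2 unit, 98% of those raised by 1.5 and 98% of those raised by 2 passed 2-fold. For all 4 constructs together 18%, 78% and 94% did, and for the localization split 66% and 98% of genes apart by 1 and 1.5 were recovered. Of 60 simulated lists of 15 unchanged genes, 0% lay outside percentiles 1 to 99, and 91.7% of lists raised by 0.5 reached percentile 99.

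The alternatives were no filter on dim genes, a filter on the mean, centring of each array on its median, repeated quantile normalization, removal of the intensity-dependent trend by lowess (span 0.3) against the mean of the 5 arrays, other fold limits, all probe sets, any 3 of the 4 constructs, and list members that passed the filter. Results without the H467A array were added after the data were seen. The number of arrays limits the precision of every value. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.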

Results

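The series set MCF-7 cells, an oestrogen receptor-positive human breast cancer line, transfected with an empty plasmid beside the same cells transfected with 4 forms of XIAP, the X-linked inhibitor of apoptosis that binds caspases through its BIR domains and carries a RING ubiquitin ligase domain. Its question was how transcript levels differ between XIAP forms that sit in different places in the cell. Per the labels, wild-type XIAP and XIAP H467A, which lacks ligase activity, were cytoplasmic. XIAP delta-RING, from which the RING domain was deleted, and XIAP NLS, which carries an added nuclear localization signal, were found in the nucleus and in the cytoplasm. RNA was collected 24 h after transfection, and each of the 5 conditions was measured on 1 Clariom S array, a short-oligonucleotide array with 24351 probe sets. With 1 array per condition no difference has a replicate check, so no error or p-value is given, and the 4 constructs were not treated as replicates of each other. Positive control probe sets lay above negative ones by a median of 6.94 log2 units on the empty vector array, 6.44 on wild type, 6.35 on H467A, 6.74 on delta-RING and 6.91 on NLS. The standard deviation of the values of named genes was 2.17, 2.001, 1.96, 2.18 and 2.14 log2 units in the same order, so both arrays of cytoplasmic XIAP had the narrower ranges. Over the 9911 genes kept after the filter on dim genes, the median difference to the empty vector was -0.13 for wild type, -0.29 for H467A, -0.07 for delta-RING and -0.05 for NLS, and the gene lists are therefore set beside random lists that carry the same shift. On at least 1 array BMP8A, BTK, CASP9, CCL20, EPSTI1, GBP5, GSG1L2, H4C6, INHBA, LINC00174, MMP13, NELL2, NKX2-2, PKP1, RAP1GAP, SLC1A2, SLC37A2 and ZAR1L, all named in the comparisons, lay at or below the level that 95% of negative controls stay under, so the size of their differences is not well determined.

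XIAP itself was higher in every construct. Its log2 level was 8.62 with the empty vector, 12.33 with wild type, 12.60 with H467A, 12.22 with delta-RING and 12.71 with NLS, which is 13.1-fold, 15.8-fold, 12.2-fold and 17.0-fold above the empty vector. The array does not separate the cell's own transcript from the plasmid's, and where the probes lie along XIAP is not given in the sources used here, so the value for delta-RING, which lacks part of the sequence, may not be on the same footing. Of the other 11 measured genes for inhibitor of apoptosis proteins, their antagonists and initiator caspases, BIRC6 alone passed 2-fold, with a difference of -1.34 in H467A. BIRC2 differed from the empty vector by -0.29 in wild type and by -0.64 in H467A, and CASP8, an initiator caspase, by -0.42 and -0.79. BIRC5, BIRC7, NAIP, DIABLO, HTRA2, XAF1, SEPTIN4 and CASP9 stayed within 2-fold of the empty vector in all 4 constructs.

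With all 4 constructs, 56 kept genes were at least 2-fold higher than with the empty vector. They included RGS2, a regulator of G protein signalling, IL6, an inflammatory cytokine, BTK, a tyrosine kinase of B cell receptor signalling, and ATF3, a stress-induced transcription factor. With the empty vector RGS2 lay at 4.89, just above the level that 95% of negative controls stay under there (4.80). The size of its differences is therefore not well determined either. RGS2 was 23.5-fold higher in wild type, 17.5-fold in H467A, 32.8-fold in delta-RING and 5.93-fold in NLS. IL6 was 19.7-fold, 14.9-fold, 19.5-fold and 4.26-fold higher in the same order, and ATF3 5.01-fold, 3.53-fold, 6.40-fold and 3.33-fold. BTK differed from the empty vector by 3.96, 3.06, 4.02 and 2.12 log2 units. RTL9, a gene derived from a retrotransposon, was between 4.91-fold (NLS) and 12.5-fold (delta-RING) higher, and GLCCI1 between 3.55-fold and 9.44-fold. VANGL2, a planar cell polarity gene, GRB10, an adaptor of the insulin receptor, and CH25H, the cholesterol 25-hydroxylase, had their smallest difference in NLS as well, at 3.51-fold, 3.45-fold and 3.10-fold. Of the 56, 9 lay within the range of negative controls with the empty vector, and EPSTI1 did so in NLS too. No kept gene was 2-fold lower in all 4. Over the 55 genes other than XIAP, the median difference was 2.44 in wild type, 1.92 in H467A, 2.74 in delta-RING and 1.28 in NLS, and NLS was the lowest of the 4 constructs for 54 of them. All 4 comparisons use the same empty vector array. In 100 simulations of unchanged arrays against 1 shared array, 19 to 44 genes (median 28) were 2-fold higher in all 4 and 31 to 63 (median 43) were 2-fold lower, with a noise level that was assumed since it was not measured. With the observed deviations of each array shuffled across genes instead, which keeps any real differences within the noise, 109 to 132 genes (median 121) were 2-fold higher in all 4, more than the 56 observed.

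**Figure D1:**
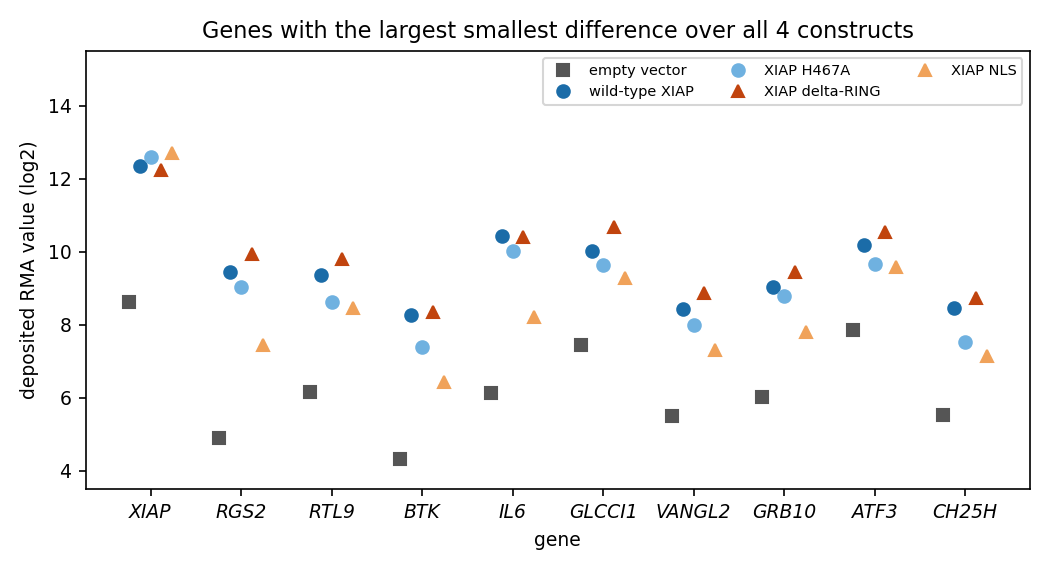
Deposited RMA values (log2, vertical axis) of the genes whose smallest difference to the empty vector over the 4 constructs was largest, with 1 point per array and a colour per condition. RGS2 goes from 4.89 with the empty vector to 9.92 with delta-RING, and XIAP is the gene for which the NLS array has the highest point, at 12.71.

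With wild-type XIAP, RGS2, IL6 and CCL20 had the largest increases. CCL20, a chemokine, was at a log2 level of 8.97 against 4.80 with the empty vector, which lay at the upper range of negative controls, and CFB, complement factor B, was 11.4-fold higher. RAET1L, a ligand of the NKG2D receptor of natural killer cells, was 8.87-fold higher, beside RGS2, IL6, BTK, RTL9, GRB10, CH25H and XIAP with the values above. The largest decreases were those of CLEC7A, a pattern recognition receptor (-2.18), SLC26A2, a sulfate transporter (-2.11), STON2, an endocytic adaptor (-1.99), GNB4, a G protein subunit (-1.80), and SLC1A2, a glutamate transporter (-1.74). SRGAP1 (-1.67), RAP1GAP (-1.63), TMEM229B (-1.59), CISH, a feedback inhibitor of cytokine signalling (-1.56), and ACSL1, an acyl-CoA synthetase (-1.53), followed. In all, 325 kept genes were at least 2-fold higher and 127 at least 2-fold lower. With each array centred on its median, the split was 264 higher and 212 lower.

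With H467A, RGS2, IL6, BTK and GRB10 were again among the genes with the largest increases. They stood beside LINC00174 (a difference of 2.87, with the limit of the filter reached on this array alone), ST3GAL2, a sialyltransferase (2.74), PLCG2, a phospholipase C (2.58), CEACAM5, the carcinoembryonic antigen (2.52), and MED12L (2.51). CLEC7A (-2.56), the interferon-induced SLFN5 (-2.11), the chemokine CCL2 (-2.04), TMEM229B (-2.01) and FRMD6 (-1.96) were lowest, followed by BCKDHB (-1.88), RHOBTB3 (-1.86), PDGFRL (-1.85), MBNL3 (-1.80) and GNB4 (-1.79). In the deposited values 219 kept genes were 2-fold higher and 502 were 2-fold lower, and this balance depended on the scaling. Centring left more lower genes, 242 higher and 416 lower. After quantile normalization 337 were higher and 225 lower, and after removal of the intensity-dependent trend 325 were higher and 178 lower.

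With delta-RING, the interferon-induced EPSTI1 and GBP5, a guanylate-binding protein, were among the genes with the largest increases. EPSTI1 was at a log2 level of 7.05 against 3.47 with the empty vector and GBP5 at 7.52 against 4.14, where both lay within the range of negative controls, as EPSTI1 did in NLS at 4.50. IGFBP6, an insulin-like growth factor binding protein, was 10.8-fold higher and RAET1L differed by 3.46, beside RGS2, IL6, BTK, RTL9, GRB10 and XIAP. MMP13, a collagenase, was lower, at a log2 level of 4.89, within the range of negative controls, against 7.75. CLEC7A (-1.94), SLC26A2 (-1.91), CCL2 (-1.75), IL20 (-1.59), STON2 (-1.55) and RHOBTB3 (-1.53) were lower, as were ABCA12 (-1.50), SRGAP1 (-1.50) and the chemokine receptor ACKR3 (-1.48). In all, 333 kept genes were 2-fold higher and 95 were 2-fold lower.

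With NLS, far fewer genes lay 2-fold from the empty vector, 60 higher and 3 lower, although XIAP was highest in this array. After XIAP, the largest increases were those of RGS2 (2.57), RTL9 (2.30), BTK (2.12), IL6 (2.09), GLCCI1 (1.83), VANGL2 (1.81), GRB10 (1.79), ATF3 (1.74) and GABARAPL1, an autophagy gene (1.68). The 3 lower genes were MMP13 (-1.33), CCL2 (-1.10) and BARD1, the partner of BRCA1 (-1.04). Genes chosen on the other 3 constructs lay on the same side of the empty vector in NLS, with smaller differences. The choice and the NLS difference share the empty vector array, so a shared side can follow from the choice without any change. Of 135 genes other than XIAP that were 2-fold higher in wild type, H467A and delta-RING, all 135 were above the empty vector in NLS, with a median difference of 0.91 against 1.95 for the mean of the other 3, and NLS was the construct closest to the empty vector for 134. Of 31 genes 2-fold lower in the other 3, all 31 were below the empty vector in NLS, with a median difference of -0.48 against -1.36, and 0 passed 2-fold there. The share of the difference seen in NLS had a median of 0.482 for the higher genes and 0.359 for the lower ones. With each array's deviations shuffled across genes, the median share for higher genes was 0.974. The robust spread of the differences was 0.19 log2 units between the empty vector and NLS arrays and 0.27 between delta-RING and NLS, and it ranged up to 0.45 for the other pairs (empty vector and H467A).

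**Figure D2:**
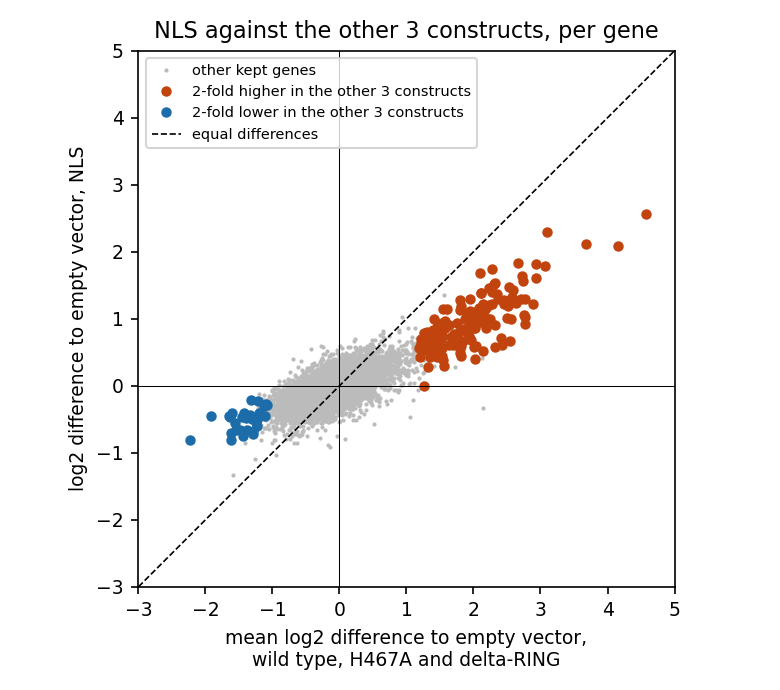
Log2 difference to the empty vector in NLS (vertical axis) against the mean log2 difference of wild type, H467A and delta-RING (horizontal axis), with 1 point per kept gene other than XIAP. Genes 2-fold higher (135) or lower (31) in the other 3 constructs are coloured, and nearly all of them lie between 0 and the dashed line of equal differences.

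Targets of the transcription factor NF-kB, which drives inflammatory genes, were higher with wild type and delta-RING. Of 18 measured members, 17 were above the empty vector in wild type and 4 of them by at least 2-fold, with a list median of 0.84 at percentile 100 among 10000 random lists (random median -0.12). In delta-RING 15 were above it, with a median of 0.42 at percentile 100, and in NLS 10 were, with a median of 0.03 at percentile 90.3. H467A had a median of 0.17 (0.11 for members that passed the filter) at percentile 99.9, which was 94.3 after quantile normalization and 97.75 after removal of the trend. IL6, also a member, differed from the empty vector by 4.30 in wild type, 3.89 in H467A, 4.29 in delta-RING and 2.09 in NLS. It thus stayed close to wild type in H467A. TNFAIP3, the feedback inhibitor A20, differed from the empty vector by 1.86 in wild type, 0.58 in H467A, 1.66 in delta-RING and 0.42 in NLS. The chemokine CXCL8 differed by 2.35, 1.27, 2.42 and 0.58, and CCL20 by 4.17, 0.23, 2.04 and -0.34. CCL2 went the other way, with differences of 0.01, -2.04, -1.75 and -1.10.

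Immediate-early genes, the transcription factors and phosphatases that cells induce first after a stimulus, stood above random lists in all 4 constructs. Their median over 19 measured members was 0.78 in wild type, 0.41 in H467A, 0.60 in delta-RING and 0.09 in NLS, at percentiles 100, 100, 100 and 99.02. In H467A, where 10 members were above and 9 below the empty vector, the median of the members that passed the filter on dim genes was -0.04, and in wild type it was 0.44 for them. In NLS the median was 0.15 after removal of the trend. ATF3, KLF4 (differences of 2.16, 1.71, 2.37 and 1.17), ZFP36 (1.66, 0.86, 1.84 and 0.62) and EGR1 (1.40, 0.91, 1.67 and 0.59) led the list.

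Interferon-stimulated genes went both ways, and the list stood above random lists in all 4 constructs. The median over 31 measured members was 0.09 in wild type, 0.03 in H467A, 0.39 in delta-RING and 0.16 in NLS, each at percentile 100, against random medians of -0.21, -0.36, -0.04 and -0.04. After removal of the intensity-dependent trend it was 0.29 in wild type and 0.40 in H467A, and after centring 0.01 and 0.07. At least 2-fold higher were 4 members in wild type, 2 in H467A, 8 in delta-RING and 2 in NLS. CXCL11, an interferon-induced chemokine, differed from the empty vector by 2.17, 1.32, 2.66 and 1.01 in the order wild type, H467A, delta-RING and NLS. HERC5, the ligase for ISG15, differed by 1.79, 1.64, 1.96 and 1.28, and ISG20, an exonuclease, by 1.55, 0.76, 2.10 and 0.53. MX2, an antiviral GTPase, was lower, by differences of -1.27, -1.17, -0.99 and -0.34. Among 10 genes for interferons and nucleic acid sensors, IFNB1 (1.58, 1.18, 2.07 and 1.14) and IFNL1 (1.23, 1.18, 1.51 and 0.80) were higher and the RNA sensor TLR3 was lower (-1.51, -1.64, -1.31 and -0.65). That list's median was 0.44, 0.57, 0.08 and 0.22, at percentiles 99.7, 99.98, 87.2 and 99.7, and wild type was at 0.15 and percentile 92.9 after quantile normalization. For the members that passed the filter the medians were 0.81 in wild type, 0.87 in H467A and 0.50 in NLS. STING1, a DNA sensing adaptor, was 1.95 higher in H467A and within 0.28 of the empty vector in the others.

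Oestrogen receptor targets stood below random lists in delta-RING and NLS, and cholesterol synthesis genes in wild type and delta-RING. Of 21 measured oestrogen receptor targets, 17 were below the empty vector in delta-RING (median -0.38, percentile 0.01) and 14 in NLS (median -0.16, percentile 0.31). In wild type the median was -0.32 and in H467A -0.49, both at percentile 1.1, inside the limits. ESR1, which encodes the receptor, differed by -1.07 in wild type, -1.10 in H467A, -0.95 in delta-RING and -0.22 in NLS, and its target GREB1 by -0.91, -1.07, -0.68 and -0.09. Of 14 measured cholesterol synthesis genes, 14 were below the empty vector in wild type (median -0.46, percentile 0.24, and -0.26 after removal of the trend) and 13 in delta-RING (median -0.47, percentile 0), with 0 members past 2-fold in either. SC5D, a sterol desaturase, differed by -0.72 in wild type and -0.73 in delta-RING, and HMGCS1, the synthase of HMG-CoA, by -0.58 and -0.50. The list was also low in H467A, with a median of -0.53 at percentile 6.0, and it was at -0.10 in NLS, at percentile 15.3.

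**Figure D3:**
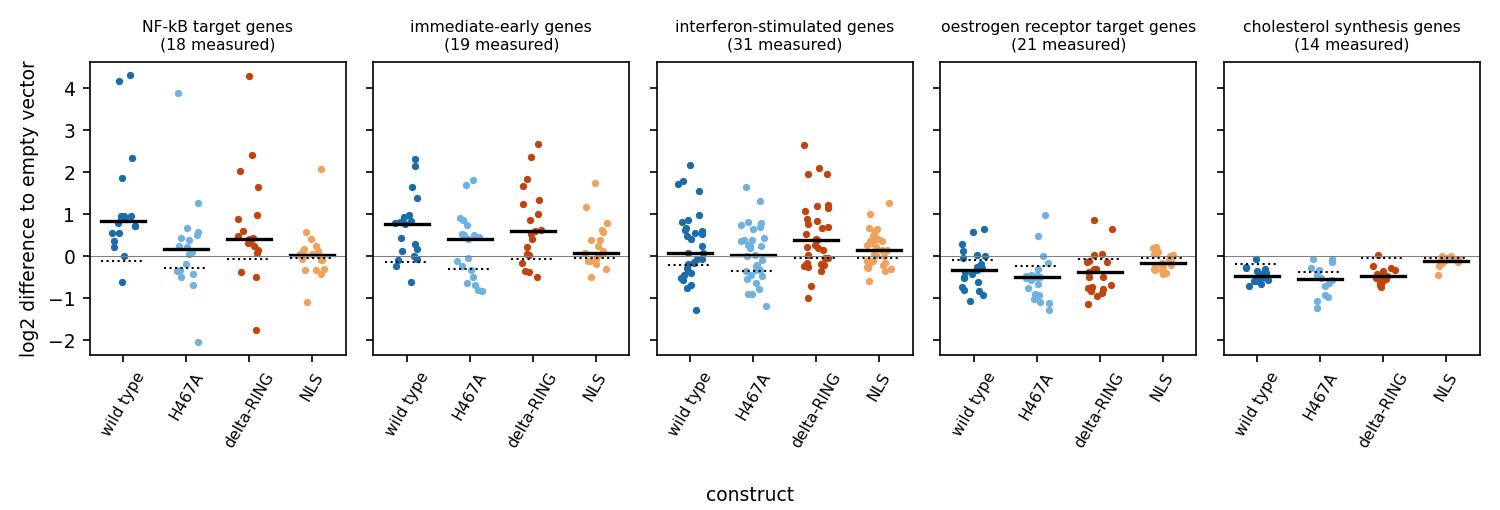
Log2 difference to the empty vector (vertical axis) of each measured member of 5 gene lists, with a point per gene and a column per construct. Solid bars give the list's median and dotted bars the median of random lists matched on level, and the NF-kB bars run from 0.84 in wild type to 0.03 in NLS.

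Several further lists passed the limit in 1 or 2 constructs. S phase genes had a median of -0.38 in wild type (percentile 0.94, and -0.22 at percentile 2.8 after quantile normalization), with RRM1 at -0.85 and MCM10 at -0.81. Stemness and drug transport genes had medians of 0.45 in H467A (percentile 99.8, and 98.95 after quantile normalization) and 0.24 in delta-RING (percentile 99.4, and 0.13 at percentile 92.9 for the members that passed the filter). Among them KLF4 and CD24 (differences of 1.26 in wild type, 1.17 in H467A, 1.71 in delta-RING and 0.60 in NLS) were higher and the drug exporter ABCG2 was lower (-1.16, -0.91, -1.23 and -0.49). In delta-RING, antioxidant genes under NRF2 had a median of -0.33 (percentile 0.20), epithelial genes -0.26 (percentile 0.25) and proteasome genes 0.12 (percentile 99.4). AKR1C1, an aldo-keto reductase of the NRF2 list, differed by -1.23 there, and the epithelial keratin KRT19 by -0.46. Integrated stress response genes had a median of 0.08 in NLS (percentile 99.3, and 98.9 after quantile normalization). Leukocyte markers had a median of 0.65 in H467A (percentile 99.02, and 98.6 after quantile normalization), on dim probe sets such as PTPRC, at 3.35 with the empty vector. In all, 26 of the 124 list medians against the empty vector lay at or beyond percentiles 1 and 99. Independent lists would give 2.48. These medians are not independent, since the lists share genes and every construct is set against the same empty vector array. A deviation of that array can therefore be counted again for each construct. Random lists were matched on level only, whereas members of a list may vary together. The value of 2.48 is thus not a measure of chance for these lists.

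The other 18 lists stayed inside these limits in all 4 constructs. BCL2 family genes had medians between -0.15 in delta-RING and 0.00 in wild type. Within that family PMAIP1, which encodes the pro-apoptotic protein NOXA, was 4.20-fold higher in wild type, 3.02-fold in H467A, 6.45-fold in delta-RING and 2.61-fold in NLS, while anti-apoptotic BCL2 differed by -1.29, -1.11, -1.45 and -0.68. The IAP family list ranged from -0.34 in H467A to 0.06 in delta-RING, and XIAP binding partners outside apoptosis from -0.32 in wild type to -0.05 in delta-RING. TGF-beta and BMP targets ranged from -0.34 in H467A to -0.09 in NLS, Wnt targets from -0.24 in delta-RING to 0.12 in wild type, and p53 targets from -0.23 in delta-RING to 0.04 in NLS. Mitosis genes lay between -0.42 in H467A and 0.13 in delta-RING, histone genes between -0.28 and 0.08, heat shock genes between -0.19 and 0.08 and autophagy genes between -0.32 and 0.09, for the same pair of constructs. Metallothionein and metal transport genes lay between -0.22 in H467A and 0.12 in delta-RING, unfolded protein response genes between -0.27 in H467A and 0.02 in wild type, hypoxia genes between -0.28 in wild type and 0.08 in NLS, and mesenchymal genes between 0.07 in delta-RING and 0.48 in wild type. Ribosomal protein genes lay between -0.33 in H467A and -0.01 in NLS, and oxidative phosphorylation genes between -0.39 in H467A and -0.05 in delta-RING. As markers of other cell types, fibroblast genes lay between -0.15 in delta-RING and 0.42 in wild type and endothelial genes between -0.34 and 0.38 in the same constructs.

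Set against wild-type XIAP, which leaves the empty vector array out, H467A was lower in inflammatory genes. The comparisons with wild type all use its single array, so a deviation of that array alone could lower the same genes in each. The empty vector was likewise below wild type in 17 of 18 NF-kB targets. All 18 measured NF-kB targets were lower in H467A than in wild type (median -0.77, percentile 0), 7 of them by at least 2-fold, and 18 of 19 immediate-early genes were lower (median -0.44, percentile 0.08, and -0.27 after quantile normalization). CCL20 had the largest decrease, at -3.94, followed by ZNF684 (-2.22), the histone gene H4C6 (-2.21), NKX2-2 (-2.18) and CLEC2D (-2.15). NELL2, at a log2 level of 6.67 in H467A against 3.67 in wild type, the desmosomal PKP1 (2.36), MRPS5 (2.24), LINC00174 (2.23) and BMP8A (1.85) were higher. ZNF684, H4C6 and NKX2-2 passed the filter on dim genes through the wild-type array alone. NELL2, PKP1, LINC00174 and BMP8A passed it through the H467A array alone, so these differences each rest on a single array. In all, 38 kept genes were 2-fold higher and 214 were 2-fold lower, a split that was 74 and 123 after centring, 108 and 153 after quantile normalization and 67 and 114 after removal of the trend.

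Between delta-RING and wild type, 15 of 18 NF-kB targets were lower in delta-RING (median -0.22, percentile 0.03, and -0.09 after centring). The lowest genes were ZAR1L (-2.64), MMP13 (-2.61), INHBA, a subunit of activin (-2.60), SLC37A2 (-2.39) and GSG1L2 (-2.22). All of these but MMP13 passed the filter on dim genes through the wild-type array alone and lay under its limit with the empty vector too. Their differences therefore rest on that array. HAUS1 (1.33), BBS9 (1.27), CXXC4 (1.22), FBXL17 (1.19) and PLEKHA5 (1.19) were highest. BCL2 family genes had a median of -0.16 (percentile 0.76), which was -0.07 at percentile 15.8 after quantile normalization and -0.02 after centring, and endothelial markers, dim here, a median of -0.83 (percentile 0.12). In all, 14 kept genes were 2-fold higher and 119 lower, a split that was 38 and 74 after centring, 26 and 83 after quantile normalization and 26 and 78 after removal of the trend.

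Between NLS and wild type, NF-kB targets were lower in NLS in 17 of 18 members (median -0.81, percentile 0), as were 15 of 19 immediate-early genes (median -0.39, percentile 0, and -0.24 for members that passed the filter). CCL20 (-4.51), CFB (-2.59), GSG1L2 (-2.33), ZAR1L (-2.28) and TFPI2, a protease inhibitor (-2.21), were lowest. Of these, GSG1L2 and ZAR1L passed the filter on dim genes through the wild-type array alone. SLC26A2 (1.66), STON2 (1.53), GNB4 (1.39), CLEC7A (1.37) and PREX1 (1.33) were highest. Cholesterol synthesis genes were higher in NLS in 14 of 14 members (median 0.39, percentile 99.9, and 0.22 after removal of the trend). Interferon-stimulated genes had a median of -0.12 (percentile 0, and -0.04 after centring and -0.21 after removal of the trend), with 18 of 31 lower. Hypoxia genes had a median of 0.31 (percentile 99.6, and 98.0 after quantile normalization) and stemness genes -0.37 (percentile 0.97, and -0.14 at percentile 8.5 after quantile normalization). In all, 42 kept genes were 2-fold higher and 175 lower, and 58 and 135 after centring.

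To see which genes followed the place of XIAP, the 4 constructs were split into pairs. ATPAF1, an assembly factor of mitochondrial ATP synthase, was higher in both nuclear and cytoplasmic forms than in both cytoplasmic ones by a gap of at least 1.13, at log2 levels of 7.23 in delta-RING and 7.41 in NLS against 6.10 in wild type and 6.10 in H467A. PRKAR2B, a regulatory subunit of protein kinase A (gap 0.87), SMAP1 (0.81), ZNF22 (0.76), CHRM1 (0.74), FBXL17 (0.74), MIS12, a kinetochore gene (0.73), FNBP1L (0.70), PATZ1 (0.66) and DDHD2 (0.66) also lay higher in the nuclear and cytoplasmic pair. VXN (gap 1.30), LINC01276 (1.12), the aldo-keto reductases AKR1C3 (0.92) and AKR1C1 (0.84), C14orf180 (0.89), FGF9 (0.87), FAM181B (0.87), the protease inhibitor SERPINA3 (0.81), EMX1 (0.81) and PABPN1L (0.76) lay lower in it. LINC01276 and FAM181B passed the filter on dim genes through the wild-type array alone and PABPN1L through the H467A array alone. VXN, C14orf180, FGF9, SERPINA3 and EMX1 passed it through the cytoplasmic arrays alone, and FBXL17 through the nuclear and cytoplasmic pair alone. For lists, a split compares the means of the pairs. NF-kB targets were lower in the mean of the nuclear and cytoplasmic pair in 16 of 18 members (median -0.22, percentile 0, and -0.33 after removal of the trend). Single constructs did not follow localization, since against the empty vector that list's median was 0.42 in delta-RING and 0.17 in H467A. Endothelial markers, dim here, had a median of -0.57 (percentile 0.16, and -0.34 after quantile normalization). Immediate-early genes were at -0.02 (percentile 0.16), with a mean of 0.06 and a median of 0.02 after centring, so their direction was not settled, and their median was -0.12 at percentile 1.6 after quantile normalization. With a gap of at least 1.5-fold, 36 kept genes were higher in the nuclear and cytoplasmic pair and 31 lower, 67 in all, where 100 simulations of unchanged arrays gave a median of 45 and at most 64. The balance was not stable: centring made it 75 higher and 25 lower and the filter on the mean 29 and 9, while it was 52 and 241 without the filter on dim genes and 105 and 232 without the H467A array. The cytoplasmic arrays were those with the narrower range of values.

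The split by RING domain, with H467A and delta-RING against wild type and NLS, gave 17 genes. YPEL3 (gap 0.62), RBFOX2 (0.61) and ST3GAL2 (0.59) were higher with the altered RING. MVB12B, which had the largest gap, POTEI (0.86), TFPI, the tissue factor pathway inhibitor (0.79), TRMT13 (0.70), EDA2R (0.70), USP31 (0.69), USPL1 (0.67), NDUFAF6 (0.66), INTS5 (0.65) and CCL2 (0.65) were lower, 14 in all against 3 higher. After centring 7 were higher and 6 lower, after quantile normalization 8 and 6, and after removal of the trend 6 and 6. Unchanged arrays gave up to 63 genes in simulations. Interferon-stimulated genes (median 0.08, percentile 100), sensing genes (0.18, percentile 99.9, and 95.8 after quantile normalization), immediate-early genes (0.10, percentile 99.9) and cholesterol genes (-0.22, percentile 0.78) stood apart in this split. After centring the medians of interferon-stimulated, immediate-early and cholesterol genes were 0.17, 0.19 and -0.13.

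The remaining split, of wild type and delta-RING against H467A and NLS, matches no single factor named in the labels. It is the interaction of localization and RING, in which the difference by RING depends on localization. The split gave 105 genes in the deposited values, 95 higher in wild type and delta-RING and 10 lower. The largest gaps among the higher ones were those of CCL20 (gap 1.81), TFPI2 (1.75), CFB (1.52), TNFAIP2 (1.24), CD44 (1.17), the NF-kB inhibitor TNIP1 (1.16) and the alarmin S100A8 (1.09), beside HTR3E, TMEM171 and SLC1A3. TASOR2 (0.97) and the cytokine OSM (0.83) had the largest gaps among the lower ones. NF-kB targets were higher in wild type and delta-RING in 16 of 18 members, with a median of 0.71 at percentile 100, immediate-early genes in 16 of 19 (median 0.44, percentile 100), interferon-stimulated genes in 23 of 31 (median 0.26, percentile 100) and mitosis genes in 19 of 20 (median 0.26, percentile 99.7). Cholesterol genes had a median of -0.07 (percentile 0.40). After quantile normalization the medians of interferon-stimulated, mitosis and cholesterol genes were 0.13, 0.15 and -0.18. The 105 genes compare with at most 54 in simulations of unchanged arrays. After quantile normalization 59 were higher and 13 lower, and after centring 72 and 9, fewer than the 100 that the localization split then gave.

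The differences of the constructs to the empty vector ran together across genes, which are not independent replicates. Pearson's r was 0.73 between wild type and H467A, 0.73 between wild type and delta-RING, 0.68 between wild type and NLS, 0.62 between H467A and delta-RING, 0.65 between H467A and NLS and 0.69 between delta-RING and NLS. Unchanged arrays against 1 shared array gave 0.45, 0.51, 0.58, 0.45, 0.51 and 0.58 in that order. The covariance was 0.199, 0.184 and 0.164 for the pairs among wild type, H467A and delta-RING (wild type with each of the others first) against a simulated 0.109. For the pairs with NLS it was 0.088, 0.088 and 0.086, below the simulated value. Wild type and delta-RING shared 221 genes that were 2-fold higher, where unchanged arrays against 1 shared array gave at most 67 in simulations, wild type and H467A shared 142 (at most 73) and H467A and delta-RING 148 (at most 75). Of the 60 genes 2-fold higher in NLS, 59 were so in wild type, 57 in H467A and 60 in delta-RING. These overlaps lay within the simulated ranges, which reached 64, 65 and 63. The simulations did not hold the number of higher genes of any construct at the observed one, such as 60 in NLS. Their covariance with NLS was above the observed one. For NLS these ranges therefore do not decide whether the overlap exceeds that of a shared array. Shuffled deviations, which keep any real differences as noise, gave 109 to 132 genes higher in all 4 constructs. Each pair then shared at least that many, and the overlaps of pairs were not counted there. The simulated noise was assumed, and the empty vector array cannot be split, so how much of each overlap comes from it is open.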

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

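The tests of differing ranges of values were set down before their results were seen, and the tests of chance, of the empty vector array, of a batch, of XIAP transcript level and of the other splits of the arrays were chosen only after the result was seen.

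A set of 11 of the 20 genes named for the localization split lay on opposite sides of the empty vector in the nuclear and cytoplasmic pair and in the cytoplasmic pair, and this difference was not tested. No kept gene was 2-fold higher in both of a pair and 2-fold lower in both of the other (0 genes), and some lay close to the empty vector, such as EMX1 at 6.17 in NLS against 6.18 and C14orf180 at 6.27 in delta-RING against 6.33. The mean of the nuclear and cytoplasmic pair minus that of the cytoplasmic pair was 0.84 for SMAP1, 1.19 for FBXL17 and 0.82 for MIS12, which were above the empty vector in the first pair. It was -1.45 for VXN, -1.49 for AKR1C3, -0.99 for C14orf180, -1.20 for FGF9, -1.22 for FAM181B, -1.40 for SERPINA3, -0.95 for EMX1 and -0.85 for PABPN1L, which were below it there. All of these but AKR1C3 passed the filter on dim genes through cytoplasmic arrays alone. Outside the named genes, 6 of 1544 unnamed probe sets whose level reached the median were 2-fold higher in all 4 constructs and 0 were lower. Among 612 negative control probe sets, of which 14 reached the median, 1 was higher and 1 was lower. Among the 63 ERCC controls, of which 3 reached it, 0 were either. Of 8 spiked bacterial controls, 1 was past 2-fold from the empty vector, a thr probe set that differed by -1.26 in wild type, -1.498 in H467A, -0.47 in delta-RING and -1.03 in NLS.

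The first pattern is the 56 genes 2-fold higher in all 4 constructs, with 0 lower and with smaller differences in NLS. At 1.5-fold 82.5% of the genes past the limit in all 4 were higher, so lower ones then appeared. An empty vector array that was alone out of place would show its whole difference in NLS too. A simulation with shuffled deviations gave a median share of 0.974, yet the median share in NLS was 0.482 with an upper quartile of 0.572. A batch that set the empty vector and NLS arrays apart to an equal degree would, as the only cause, leave almost none of it. Yet the lower quartile was 0.390. A batch that placed NLS between the empty vector and the other arrays could alone leave part of the difference. An equal batch together with a response to XIAP could do so too. The values do not tell either apart from a weaker response in NLS. The empty vector and NLS arrays held 80 identical values and had the smallest robust spread of any pair (0.19). Less XIAP transcript in NLS is argued against by its XIAP difference, 1.085 of the mean of the other 3, and unequal ranges by the 53 genes counted after quantile normalization. Chance passed through the single empty vector array stays open, since the noise of a single array was not measured. With an assumed noise, simulations gave up to 44 higher genes against the 56 observed, and 31 to 63 lower genes against 0. At that noise no simulation gave as many higher genes or as few lower ones. Shuffled deviations gave 109 to 132 higher genes, but they keep any real differences as noise, so their count does not decide. A combination of these explanations was not tested. A response to XIAP that is weaker with the NLS form may account for the pattern, as an untested hypothesis.

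The second pattern is the 67 genes that separated nuclear and cytoplasmic from cytoplasmic XIAP. The narrower overall range of both cytoplasmic arrays as its whole cause is argued against by the 66 genes counted when quantiles were made equal. After removal of the intensity-dependent trend 51 were left, fewer than the 64 that simulations of unchanged arrays reached for the deposited values. That count argues against nothing. Both cytoplasmic arrays also had the smaller distance between positive and negative controls (6.44 and 6.35), so localization and array quality cannot be told apart. Of the 3 ways to pair the 4 arrays, 2 gave as many genes in the deposited values, with 105 in the highest other split (81 after centring, where localization gave 100), and 3 splits are too few for a share under 0.05. The other splits carry RING and its interaction with localization, so their counts are not a measure of chance alone. The place of XIAP may therefore account for these genes only as an untested explanation.

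The third pattern is the higher level of NF-kB targets in wild type and delta-RING than in H467A and NLS. That split follows no single label and is the interaction of localization and RING. The pattern was not particular to these targets. The 55 genes other than XIAP that were higher in all 4 constructs had median differences of 2.44 in wild type and 2.74 in delta-RING. In H467A and NLS these were 1.92 and 1.28. Whether the NF-kB pattern only follows that size was not tested. Unequal ranges are argued against by the list's median, 0.709 as deposited and 0.658 after removal of the intensity-dependent trend. Less XIAP transcript in H467A and NLS than in wild type was not seen, since XIAP was higher in both than in wild type by at least 0.267 log2 units. The largest robust spread between these arrays was 0.181 over 142 genes of high level. Such a spread is not a bound on unchanged genes, so with 1 array per condition less transcript is not excluded. The XIAP value of delta-RING, which lacks part of the sequence, may be too low, so the comparison with that construct stays open. Wild type and delta-RING share neither localization nor RING state in the labels. With 1 array per condition, an interaction of localization and RING was not told apart from deviations of single arrays. Protein level and plasmid uptake were not measured here.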

How the results depend on the processing

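The values without the H467A array were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because each group has 1 array, whose replicate number is only a name. Counts moved with the filter, the fold limit, the number of constructs required and the H467A array. Without the filter on dim genes, the numbers past 2-fold were 964 for wild type, 1234 for H467A and 653 for delta-RING against the empty vector, 695 for H467A, 695 for delta-RING and 608 for NLS against wild type, and 293 for the localization split. With the filter on the mean they were 132, 39 and 124 against wild type and 38 for the localization split. At 1.5-fold they were 1825, 3024, 1299 and 251 for wild type, H467A, delta-RING and NLS against the empty vector, 1422, 971 and 1044 for H467A, delta-RING and NLS against wild type, and 177 in all 4 constructs (82.5% of them higher). At 3-fold they were 136, 117, 172 and 12, then 34, 24 and 41, and 11 in all 4. In any 3 of the 4 constructs 174 genes passed, 80.5% of them higher. The localization split gave 3 genes at a 2-fold gap, 717 at a smaller gap than the 1.5-fold used, and 337 without the H467A array, where fewer arrays must be separated. The median correlation between constructs was 0.69 and 0.56 without the filter. Centring, quantile normalization, removal of the trend and all probe sets kept each of these counts within 1.5 times, though not its balance of higher and lower genes. The balance also turned with the fold limit, to 797 higher and 1028 lower for wild type at 1.5-fold and to 83 and 34 for H467A at 3-fold against the empty vector. The 4 XIAP differences kept their size. For immediate-early genes the median in H467A turned to -0.0444 for members that passed the filter, and the localization median turned to 0.0185 with centring and 0.12 for members that passed the filter. Of 502 other recomputed values of named genes and lists, 479 kept their sign and shifted by less than 0.2 log2 units (lists) or than the robust spread of the comparison (genes), 20 shifted by more and these 3 reversed. Such small shifts still ended calls: of 49 list medians at or beyond percentiles 1 and 99 over all comparisons, 12 came back inside under at least 1 alternative, 7 of them against the empty vector. Apart from fewer genes, members or arrays entering a count, the cause was not tested. The smaller distance between positive and negative controls on the wild-type and H467A arrays (6.44 and 6.35) limits what dim genes show there.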

Other observations

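The gene lists in this part were built only after some of their members had been seen among the genes higher in all 4 constructs, so they describe those genes and test nothing. Of 8 ligands of NKG2D, the receptor by which natural killer cells recognise stressed cells, 5 were at least 2-fold higher than the empty vector in wild type, 4 in H467A, 4 in delta-RING and 3 in NLS. The higher ones were of the ULBP and RAET1 group: RAET1L differed by 3.15, 2.18, 3.46 and 1.61 in that order, ULBP2 by 2.26, 1.59, 2.30 and 0.93 and ULBP3 by 2.01, 1.83, 2.52 and 1.38. MICA (-0.11, -0.58, 0.08 and 0.09) and MICB (-0.30, -0.29, 0.03 and -0.16) stayed within 2-fold. The sequences of ULBP and RAET1 genes are related, so their probe sets are not independent measurements.

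Of 10 feedback genes of the MAPK pathway, 3 were 2-fold higher in wild type, 1 in H467A, 3 in delta-RING and 1 in NLS, with medians of 0.60, 0.12, 0.44 and 0.06. SPRY2, an inhibitor of receptor tyrosine kinase signalling, differed by 2.69 in wild type, 2.02 in H467A and 2.95 in delta-RING, whereas SPRED1 differed by -0.67, -0.66 and -0.42 in the same order. Of 5 PLAAT genes, which encode phospholipases and acyltransferases, PLAAT4 (2.07, 1.88, 2.75 and 1.46) and PLAAT2 (1.35, 1.32, 1.95 and 1.15, near background with the empty vector) were 2-fold higher in all 4 constructs and the other 3 in none.

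Interferon genes were already measured at high values with the empty vector, at log2 levels of 9.53 for IFNB1 and 11.33 for IFNL1, before the differences given for the constructs. No untransfected culture was analysed here, so the part that transfection itself plays in these levels is not known. The arrays of the empty vector and NLS held 80 identical values among the 24351 probe sets, where no other pair held more than 1, and differed past 2-fold in 63 kept genes, where the other 9 pairs differed in 133 to 721.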
